A study of Mus musculus with 2 samples.

How the data were processed

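Leukocytes from subcutaneous B16-F10 tumours, a mouse melanoma line grown in C57BL/6 mice, were sorted by FACS as CD45-positive and negative for the viability dye DAPI, per the labels' protocols. The series' design text writes the DAPI sign of live cells the other way round, and the protocol was followed here. Droplet libraries were made with 10x Genomics Chromium 3′ v3 chemistry. There was 1 library from control mice and 1 from mice given an agonist antibody against OX40. How many mice were pooled in each library is not given in the sources used here.

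The deposited matrices hold UMI counts (unique molecular identifiers, 1 per captured RNA molecule) per gene and cell barcode, as whole numbers without normalization. Per the submitters' processing notes they were made with Cell Ranger on genome build mm10, and per the file headers the software version was 3.1.0. The barcodes had already passed the authors' cell calling, and the lowest deposited barcode holds 500 UMIs. Both matrices list the same 31053 genes, with gene symbols as deposited. Positions of named genes were looked up by gene ID in GENCODE release M21, assembly GRCm38, which is the same build as mm10. All 332 named genes were found there.

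Barcodes with at least 500 UMIs, at least 200 genes and at most 10% mitochondrial UMIs were used. This left 6354 of 7187 control barcodes and 7500 of 8569 treated barcodes. A doublet score was computed per library as Scrublet defines it, with 2 simulated doublets per cell, and the highest scores were removed at 0.8% per 1000 barcodes. That removed 365 control and 514 treated barcodes and left 5989 and 6986 kept cells. The score's automatic threshold marked 0.0157% of control and 0% of treated barcodes, below the 0.5% set beforehand, and was therefore not used.

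Counts were scaled to 10000 per cell and log transformed. The 2000 most variable genes within library, without mitochondrial, ribosomal, receptor segment, Xist and cell cycle genes, gave 30 principal components. A shared-neighbour graph of 15 neighbours was clustered with the Leiden algorithm at resolution 1.0, both libraries together, and T and NK clusters were clustered again. Clusters were named from 24 marker lists fixed before the data were examined. The scoring rule was not fixed then and was revised while the clusters were being inspected, from a mean fold to a median fold and then to the form used. In its final form a cluster takes the class with the highest mean log2 fold of its markers over all other kept cells, and a marker with a UMI in under 5% of the cluster's cells adds nothing positive. A cluster stayed unnamed with a score under 1, with under 3 detected markers, with more markers of another class than its own among its top 10 genes, or with a low UMI count and under 3 own markers among them. A T cell subcluster with macrophage markers at least 2 log2 units above the other T and NK clusters also stayed unnamed. Monocyte and macrophage clusters, which grade into each other, form 1 class called mononuclear phagocytes, and B and plasma cells form another. Shares of unnamed clusters are given with the results.

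With 1 library per group no test was possible, so no p-value or replicate spread is given. Shares carry exact Clopper-Pearson 95% intervals. Summed UMIs carry exact Poisson 95% intervals, and ratios an exact interval conditional on both counts. All intervals cover counting error only, not differences between animals or preparations. Those of summed UMIs take each UMI as independent, so they also leave out variation between the cells of a library and are too narrow where few cells hold many UMIs. Gene levels are in CPM, the summed UMIs of a gene in a class scaled by the class's total UMIs, and log2 ratios were taken after adding 10 CPM to both libraries. Of 27 gene lists fixed before the data were examined, members at 10 CPM or more in either library were used. The median log2 ratio of a list is given with its percentile among 10000 random lists matched in 20 bins of mean CPM, which describes these libraries and is not a p-value. The interval of a list median comes from 500 Poisson redraws of the counts.

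Named genes follow a rule fixed before the data were examined. In classes with at least 100 kept cells per library, they had at least 50 CPM, 30 UMIs and a UMI in 5% of cells in the higher library. Their class CPM in the higher library was at least 0.5 times that library's CPM over all cells, except in the sum over all cells. The Poisson intervals did not overlap and the absolute log2 ratio was at least 1. The 5 highest and 5 lowest were taken, or 10 and 10 in mononuclear phagocytes and over all kept cells. Mitochondrial, ribosomal protein, Gm and Rik genes and receptor segments were left out. Up to 4 members with the largest absolute log2 ratio of each described list, Tnfrsf4 and Tnfsf4, and the class markers were added. Shares of cells with a UMI were computed after thinning each cell to 1000 UMIs, except in the naming rules and where called unthinned. A cell was counted as cycling with UMIs of at least 2 genes of the G2M list.

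The statistics were tested on simulated data. Counts of 2640 genes were drawn from the control mononuclear phagocytes, with 200 genes changed by known folds. Of 100 genes changed 4-fold, 100% met the size, level and interval parts of the naming rule, and 0 of 2440 unchanged genes did. In the same simulation for regulatory T cells, with 2926 genes, 93% of the genes changed 4-fold were found. The simulated counts were Poisson draws of sums, without variation between cells or animals. They check the calculation and do not give the error of the rule on the real libraries.

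Alternatives fixed beforehand were a minimum of 1000 UMIs, 5% and 20% mitochondrial limits, no doublet removal, Leiden resolutions of 0.5 and 2.0, libraries clustered separately, genes centred within library and a per-cell marker gate. For gene levels they were trimmed-mean scaling, a pseudocount of 1 CPM, means over cells, thinned cells and a minimum of 20 CPM. Others, named in the closing section, were added after seeing the data. Analyses used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scikit-image 0.26.0, leidenalg 0.10.2 and igraph 0.11.9, and figures matplotlib 3.10.9.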

Results

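Single-cell RNA profiles of tumour-infiltrating leukocytes were compared between mice given an agonist antibody against OX40 (Tnfrsf4, a costimulatory receptor of activated T cells) and control mice. The question was how the treatment alters the leukocytes of B16-F10 melanomas. The control library held 7187 barcodes and 114026695 UMIs, with a median of 8927 UMIs per barcode. The treated library held 8569 barcodes and 118059108 UMIs, with a median of 7309. After filtering, 5989 control and 6986 treated cells were kept. Each group is 1 library, so differences have no replicate check and describe these libraries. Intervals in parentheses are 95% counting intervals.

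CD8 T cells made up a smaller share of the treated library, and regulatory T cells, mature migratory dendritic cells (DCs) and neutrophils a larger one. CD8 T cells were 25.4% (24.3 to 26.5) of kept control cells and 17.3% (16.5 to 18.2) of kept treated cells, a ratio of 0.683 (0.633 to 0.737). Regulatory T cells, the Foxp3-expressing suppressive lineage, were 3.81% (3.34 to 4.32) and 5.43% (4.91 to 5.98), a ratio of 1.43 (1.21 to 1.69). There were 6.67 CD8 T cells per regulatory T cell in the control library and 3.20 in the treated library. Mature migratory DCs, marked by Ccr7 and Fscn1, were 3.72% (3.26 to 4.23) and 6.06% (5.51 to 6.64). Neutrophils were 0.885% (0.664 to 1.16) and 2.20% (1.87 to 2.58), from 53 and 154 cells. Their median depths of 1712 and 1407 UMIs lie near the minimum of 500 UMIs per barcode, which can set their share. The ratio for regulatory T cells was 1.09 without doublet removal, where the class took in 532 control and 687 treated cells.

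Mononuclear phagocytes were the largest class in both libraries, at 40.6% (39.3 to 41.8) and 42.4% (41.2 to 43.5). NK cells were 4.86% (4.33 to 5.43) and 4.25% (3.79 to 4.75), and type 2 conventional DCs (cDC2) 3.77% (3.31 to 4.29) and 4.04% (3.59 to 4.52). For these 3 classes the interval of the ratio included 1. Type 1 conventional DCs (cDC1) were 1.20% (0.942 to 1.51) and 1.80% (1.50 to 2.14). Plasmacytoid DCs rested on 17 and 43 cells, a ratio of 2.17 (1.21 to 4.06) that was 1.08 without doublet removal, B or plasma cells on 16 and 51, and gamma-delta T cells on 15 and 12. The ratio for B or plasma cells was 2.73 (1.53 to 5.13), but 0.282 when each library was clustered on its own.

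Despite the CD45 sort, 384 control and 564 treated cells carried the melanoma markers Pmel, Mlana and Dct, with medians of 76082 and 68035 UMIs per cell. They were 6.41% (5.80 to 7.06) and 8.07% (7.44 to 8.74) of kept cells. Whether they passed the sort by carry-over or bound to CD45-stained leukocytes was not resolved, so their share is not a tumour content and their levels describe only the cells that passed. Unnamed clusters held 8.57% of control and 6.94% of treated cells. Within these, unnamed T or NK clusters held 4.44% and 4.07%, a share that the naming rule, revised after seeing the clusters, kept out of the T cell classes.

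**Figure D1:**
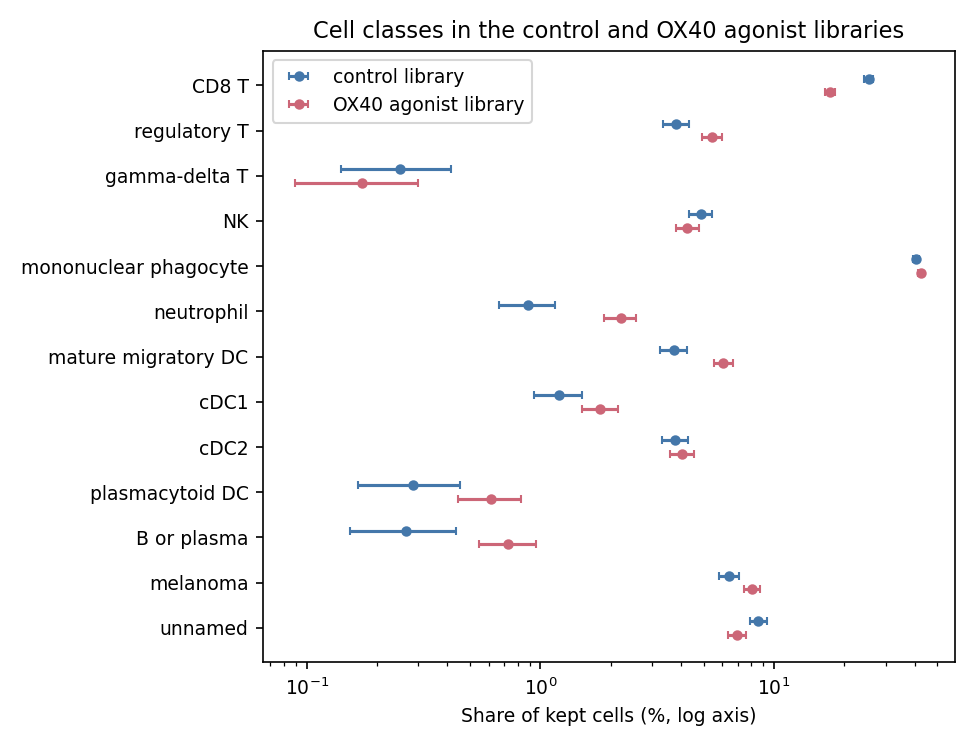
Share of kept cells in each class, in percent on a log axis, for the control library (blue) and the OX40 agonist library (red); bars are exact binomial 95% intervals. CD8 T cells lie lower in the treated library (17.3% against 25.4%), and regulatory T cells, mature migratory DCs and neutrophils higher.

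In mononuclear phagocytes, genes induced by interferon-gamma and genes of antigen presentation were lower in the treated library. The class joins 5 clusters, whose leading genes were ranked over both libraries together. The most populous in the control library (811 of 2431 cells) was scored as monocyte, with Saa3, Ly6i and Il1b as top genes. In the treated library it was the cluster led by Arg1 and Spp1 (961 of 2959 cells). Leading genes were ranked by fold with no minimum share of cells. They can thus rest on few cells, as with Saa3, whose treated UMIs came in large part from 1 cell. All 15 measured members of the interferon-gamma response list were lower, with a median log2 ratio of -0.75 (-0.77 to -0.68), percentile 0 of the random lists. Gbp4, a guanylate-binding protein, was at 95.8 CPM in the control and 35.3 in the treated library, 0.368-fold (0.344 to 0.395). Iigp1 (ENSMUSG00000054072), an immunity-related GTPase on chromosome 18 (60376027 to 60392634, mm10), was 0.383-fold (0.359 to 0.408). The T cell attracting chemokines Cxcl9 and Cxcl10 were 0.571-fold (0.561 to 0.581) and 0.589-fold (0.578 to 0.601). All 16 MHC class I presentation genes were lower, with a median of -0.50, as were 9 of 10 MHC class II presentation genes, with a median of -0.60. The peptide transporter subunit Tap1 was 0.644-fold (0.617 to 0.671). The class II chains H2-Aa and H2-Ab1 were 0.627-fold (0.620 to 0.633) and 0.624-fold (0.617 to 0.631). With the mix of the 5 clusters held at that of the control library, an alternative added after seeing the data, the medians were -0.38 (-0.44 to -0.35) for interferon-gamma response, -0.25 (-0.27 to -0.24) for MHC class I and -0.19 (-0.22 to -0.17) for MHC class II. Genes of these lists were not left out when the clusters were formed, so cluster mix and gene level are not separate measurements. H2-Q4 (0.530-fold) and H2-Q7 (0.609-fold) have near-identical relatives, so their separate values are uncertain.

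Of 13 inflammatory myeloid genes, 8 were lower and 5 higher, with a median of -0.18, between -0.25 and -0.01 over the alternatives. The largest difference in this list was that of Saa3, which was higher and is given below with its limit. Acod1, which makes itaconate, was at 151 CPM in the control and 70.1 in the treated library, 0.463-fold (0.440 to 0.487), with a log2 ratio of -0.64 after thinning. Nos2, inducible nitric oxide synthase, was 0.508-fold (0.468 to 0.550). All 7 members of the Fc receptor list were lower, with a median of -0.22, or -0.10 after thinning, led by Fcgr4 at 0.637-fold (0.617 to 0.657). Of 15 type I interferon response genes, 13 were lower, with a median of -0.24.

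Fcrls, Igf1, Gas6 and Cbr2 were the genes higher by the size rule in treated mononuclear phagocytes. Fcrls (ENSMUSG00000015852), on chromosome 3 (87250758 to 87263738, mm10), was at 29.7 CPM in the control and 125 in the treated library, 4.21-fold (3.92 to 4.52). The growth factor Igf1 was 2.95-fold (2.77 to 3.14), the TAM receptor ligand Gas6 2.82-fold (2.62 to 3.03) and the carbonyl reductase Cbr2 2.84-fold (2.61 to 3.09). The cluster led by Fcrls, Gas6 and Igf1 held 147 of 2431 control and 573 of 2959 treated cells of the class, and since these genes define it, its size and their levels are not separate measurements. The levels did not differ alike in all 5 clusters. In the clusters led by Ccl8 and C1qa and by Hp and Chil3 the log2 ratios were -0.19 and -0.05 for Igf1, -0.38 and 0.18 for Gas6 and 0.56 and 0.02 for Fcrls. In the clusters led by Arg1 and Spp1, by Saa3 and Ly6i and by Fcrls and Gas6 they were 0.83, 0.30 and 0.91 for Igf1. There they were 0.87, 0.26 and 0.69 for Gas6 and 0.90, 0.66 and 1.41 for Fcrls. In the lipid and complement macrophage list, 11 of 15 members were higher, with a median of 0.13, or 0.05 without doublet removal, led by the lipid carrier Apoe at 1.96-fold (1.94 to 1.98). The alternatively activated macrophage list went both ways, with 6 of 11 members higher and 5 lower and a median of 0.03, whose interval included 0. Over the alternatives this median lay between -0.04, without doublet removal, and 0.25, at most 5% mitochondrial UMIs. Among them the folate receptor Folr2 was 1.92-fold (1.80 to 2.05) and the scavenger receptor Stab1 1.66-fold (1.59 to 1.73), while the lectin Mgl2 was 0.603-fold (0.570 to 0.638), with a log2 ratio of -0.24 after thinning. Saa3, an acute phase protein of the inflammatory myeloid list, was 8.59-fold (7.55 to 9.80), from 8.16 CPM in the control library, but 41.0% of its treated UMIs came from 1 cell.

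RNA of T and NK cells was also lower in treated mononuclear phagocytes. The cytotoxic effector list had a median of -0.73, with Gzmb at 62.3 and 13.5 CPM, or a log2 ratio of -0.32 without doublet removal, and Cd3e at 30.8 and 11.7 CPM. In CD8 T cells themselves Gzmb was at 2306 and 2137 CPM. When mononuclear phagocytes were clustered again without 171 genes that differed between the libraries, a choice made after seeing the data, a cluster led by Ctla4, Tnfrsf4 and Cd2 held 124 control and 73 treated cells, 5.10% and 2.47% of the class, a ratio of 0.484 (0.357 to 0.651). Without these cells the cytotoxic effector median was -0.22 over the 6 members, of 11, that stayed above the minimum level, and the interferon-gamma response and MHC class I medians were -0.76 and -0.48.

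**Figure D2:**
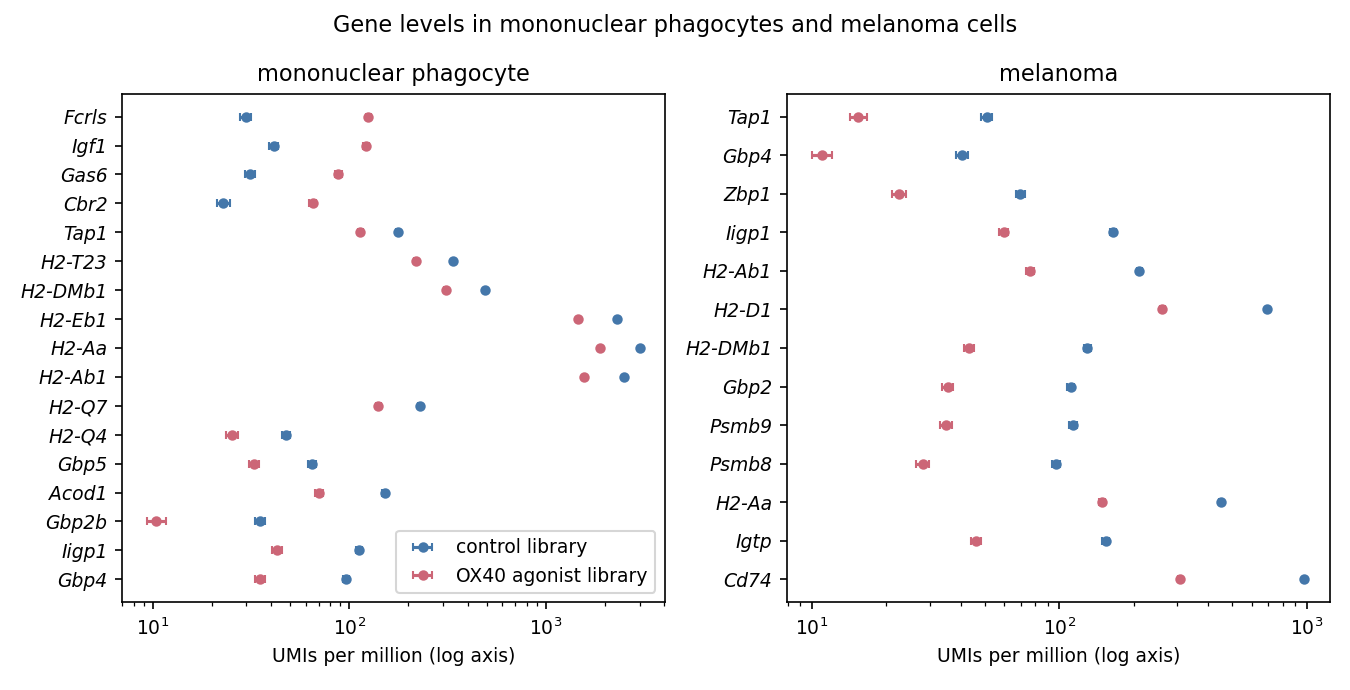
Summed UMIs in CPM (log axis) of named genes in mononuclear phagocytes (left) and melanoma cells (right), for the control library (blue) and the OX40 agonist library (red); bars are exact Poisson 95% intervals. Fcrls, Igf1, Gas6 and Cbr2 lie higher in treated mononuclear phagocytes, and the interferon-inducible and antigen presentation genes lie lower in both classes.

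The melanoma cells showed the same direction. All 11 measured interferon-gamma response genes were lower in the treated library, with a median of -1.14 (-1.20 to -1.07), as were all 13 MHC class I presentation genes, with a median of -1.04 (-1.05 to -1.02). The GTPases Igtp and Gbp2 were 0.299-fold (0.283 to 0.316) and 0.319-fold (0.299 to 0.339), and Iigp1 was 0.362-fold (0.345 to 0.380). The immunoproteasome subunits Psmb8 and Psmb9 were 0.289-fold (0.269 to 0.309) and 0.307-fold (0.288 to 0.326). H2-D1, a class I heavy chain, was at 694 CPM in the control and 261 in the treated library. All 8 MHC class II presentation genes were lower, with a median of -1.35, including H2-DMb1 at 0.333-fold (0.315 to 0.353). All 14 type I interferon response genes were lower, with a median of -0.77, led by the nucleic acid sensor Zbp1 at 0.325-fold (0.2999 to 0.351), with a log2 ratio of -1.92 after thinning. Leukocyte RNA differed in these droplets, where 12 leukocyte genes had a median CPM of 1.92% of their leukocyte level in the control and 0.992% in the treated library.

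Glycolysis and hypoxia genes of the melanoma cells were lower as well, and S phase genes higher. All 14 glycolysis genes were lower, with a median of -0.33, led by the glucose transporter Slc2a1 at 0.622-fold (0.598 to 0.647) and Eno1 at 0.653-fold (0.644 to 0.662). Of 12 hypoxia response genes, 11 were lower, with a median of -0.33, including Car9 at 0.674-fold (0.653 to 0.696). The dissociation stress list, a sign of sample handling, was lower to a like degree, with 13 of 15 members lower and a median of -0.36, or -0.08 without doublet removal. All 16 oxidative phosphorylation genes were higher, with a median of 0.08, as were 11 of 14 fatty acid and cholesterol synthesis genes, with a median of 0.15. All 14 S phase genes were higher, with a median of 0.17, led by Mcm3 at 1.24-fold (1.19 to 1.30). The share of cycling melanoma cells was 34.9% (30.1 to 39.9) and 39.5% (35.5 to 43.7), a difference within counting error. At Leiden resolution 2.0 the melanoma cells formed a cluster led by Car9 and Pgf (166 control and 163 treated cells) and another led by Serpinh1 and Rhox5 (218 and 401 cells). Within these clusters, as an alternative added after seeing the data, the medians were -0.16 and -0.07 for hypoxia, -0.16 and -0.28 for glycolysis, -0.15 and -0.24 for dissociation stress and 0.08 and 0.03 for S phase.

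Interferon-gamma response genes were lower in DCs too. In cDC2, 13 of 14 interferon-gamma response genes were lower, with a median of -0.41 (-0.54 to -0.34), and Iigp1 was 0.442-fold (0.349 to 0.557), with a log2 ratio of -1.80 after thinning. The chemokine Ccl4, also a T and NK cell product, was 0.439-fold (0.402 to 0.478). RNA of T and NK cells in the same cells was lower too under most settings, with Nkg7 at 26.5 and 9.31 CPM and a cytotoxic effector median of -0.59. At 20% mitochondrial UMIs the log2 ratio of Nkg7 was 0.27 and the median 0.25, while under the other alternatives the median lay between -0.855 and -0.13. Il12b, a subunit of interleukin 12, was at 31.1 CPM in the control and 108 in the treated library, 3.47-fold (2.70 to 4.50), but 55.6% of its control and 26.3% of its treated UMIs came from 1 cell each, and its log2 ratio lay between 0.41 and 2.30 over the alternatives. The heat shock gene Hspa1b was 0.387-fold (0.305 to 0.488), but its log2 ratio was 0.17 when each library was clustered on its own. All 14 S phase genes were lower in cDC2, with a median of -0.39 that was -0.0029 after thinning. In mature migratory DCs, 12 of 14 interferon-gamma response genes were lower, with a median of -0.23 (-0.31 to -0.15), led by Cxcl9 at 0.402-fold (0.329 to 0.490), with a log2 ratio of -0.15 without doublet removal. In these cells Nkg7 was at 68.9 and 18.5 CPM, with a log2 ratio of -0.81 at 20% mitochondrial UMIs, and Apoe at 17.3 and 54.2 CPM, with a log2 ratio of 0.60 with at least 1000 UMIs per cell, and 11 of 13 lipid and complement macrophage genes were higher, with a median of 0.37 that was -0.02 after thinning. The tubulin Tubb2b was 3.03-fold (2.36 to 3.92), with a log2 ratio between 0.31 and 1.57 over the alternatives. Cxcl2, a neutrophil attractant, was 2.60-fold (2.20 to 3.08), but 40.7% of its treated UMIs came from 1 cell, and its log2 ratio was 0.24 with at least 1000 UMIs per cell.

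**Figure D3:**
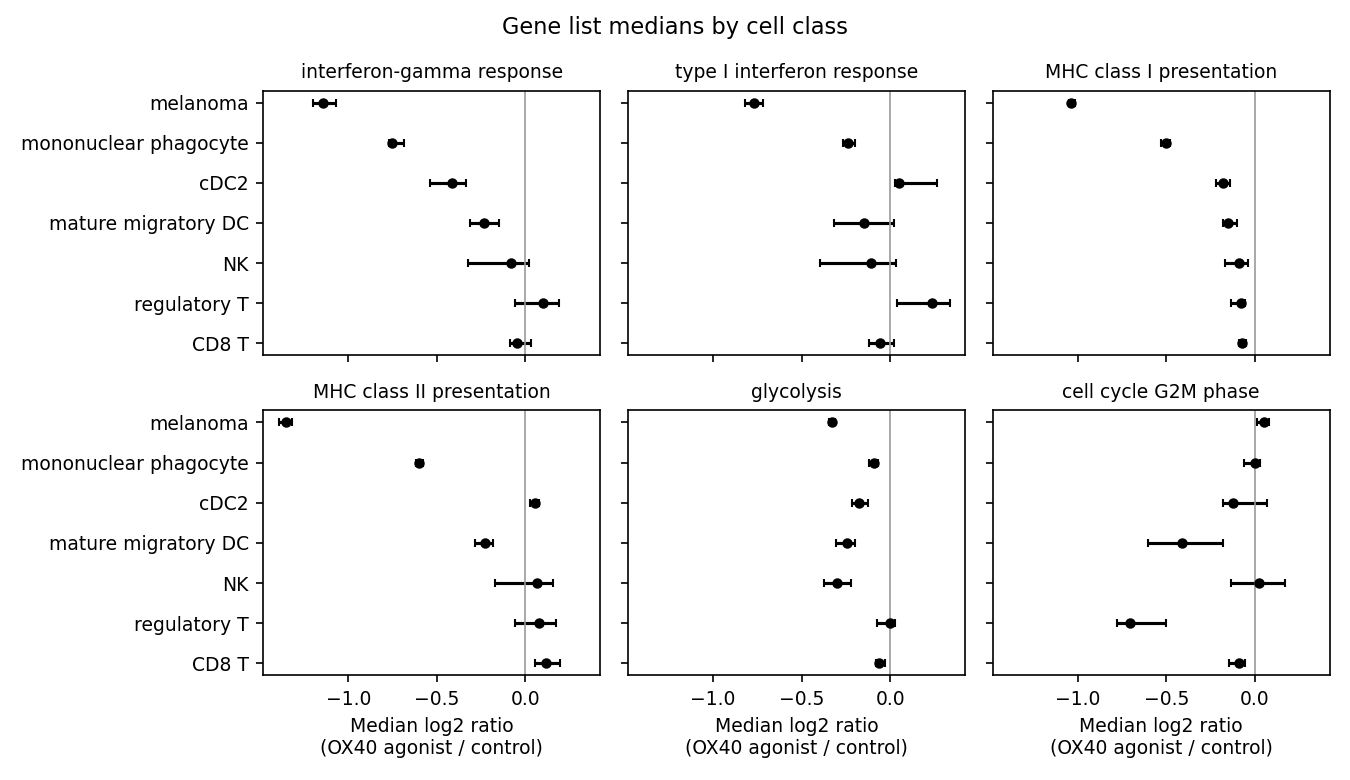
Median log2 ratio (OX40 agonist over control) of 6 gene lists in 7 cell classes; bars are 95% intervals from Poisson redraws of the counts. Among these 7 classes, which leave out neutrophils and cDC1, the interferon-gamma response and MHC class I medians lie lowest in melanoma cells (-1.14 and -1.04) and mononuclear phagocytes (-0.75 and -0.50).

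The list medians of CD8 T cells lay nearer to 0 than those of mononuclear phagocytes for interferon-gamma response and MHC class I genes. The interferon-gamma response list had a median of -0.05 (-0.09 to 0.03), or -0.11 as a mean over cells. The cytotoxic effector list had a median of -0.03 (-0.05 to 0.00), or 0.07 when each library was clustered on its own. Of 16 MHC class I presentation genes 12 were lower, with a median of -0.07 (-0.09 to -0.05). Ifng was at 571 CPM in the control and 542 in the treated library, a ratio of 0.949 (0.923 to 0.976), or 8.77 and 6.68 UMIs per cell at unequal depths. The naive and central memory list had 6 of 7 members higher, with a median of 0.20 (0.11 to 0.27), or 0.09 when each library was clustered on its own, and the dissociation stress list 14 of 17, with a median of 0.14. A subcluster with the naive and central memory genes Tcf7, Satb1, Lef1 and S1pr1 among its top genes stayed unnamed. Its 169 control and 160 treated cells are not in the CD8 T class, so the list median leaves them out. The inhibitory receptor list had 7 of 9 members higher, with a median of 0.10, or 0.20 after thinning. The chemokine Ccl1 was 0.588-fold (0.563 to 0.614). The only gene past the size rule was Spp1, 0.398-fold (0.378 to 0.418), with a UMI in 9.63% (8.19 to 11.2) of control and 5.05% (3.88 to 6.44) of treated cells after thinning, and in 34.1% and 25.7% unthinned. In mature migratory DCs, taken as background with median depths of 8498 and 7411 UMIs, 5 of 220 and 4 of 421 thinned cells had a Spp1 UMI. Spp1 is abundant in the mononuclear phagocytes, at 1304 and 1429 CPM. Cycling CD8 T cells were 35.0% (32.6 to 37.5) and 34.1% (31.4 to 36.9) after thinning, and 79.9% and 71.9% unthinned. In mature migratory DCs, again as background, the thinned cycling shares were 3.64% and 1.66%.

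Regulatory T cells had lower mitotic gene levels in the treated library. The class joins a subcluster of 193 control and 337 treated cells, with median depths of 4455 and 3801 UMIs, and a deeper subcluster of 35 and 42 cells, at 14004 and 12842.5 UMIs. Sums weigh the deeper cells more, and the mix of these subclusters was not held the same. All 15 G2M phase genes were lower, with a median of -0.70 (-0.78 to -0.50), or -0.41 when each library was clustered on its own, including Cenpf at 0.321-fold (0.249 to 0.412), or a log2 ratio of -0.71 after thinning, and Ube2c at 0.422-fold (0.363 to 0.490). Outside the list, Prc1, Reep4 and Kif20b were 0.440-fold, 0.404-fold and 0.437-fold. Without doublet removal the log2 ratios were -0.71 for Ube2c, -0.53 for Prc1, -0.59 for Reep4 and -0.56 for Kif20b, and after thinning that of Reep4 was -0.49. The share of cycling regulatory T cells was 17.4% and 14.4% after thinning, a ratio of 0.830 (0.538 to 1.29), so a difference was not detectable at this depth. Ccl3 was 2.22-fold (1.82 to 2.71), but 41.0% of its treated UMIs came from 1 cell and its log2 ratio was -0.14 as a mean over cells. Ifng was 1.65-fold (1.31 to 2.09), from 108 and 240 UMIs, but 46.2% of its treated UMIs came from 1 cell, its log2 ratio was -3.15 when each library was clustered on its own, and the thinned share of cells with a UMI had a ratio of 0.818 (0.402 to 1.70). Of 14 interferon-gamma response genes, 8 were higher and 6 lower, with a median of 0.10 (-0.06 to 0.19), or -0.10 without doublet removal. Of 9 type I interferon response genes, 7 were higher, with a median of 0.24 (0.04 to 0.34), or -0.01 after thinning.

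In NK cells, 14 of 15 glycolysis genes were lower, with a median of -0.30 (-0.38 to -0.22), and all 14 S phase genes, with a median of -0.27, or -0.08 at most 5% mitochondrial UMIs. Lower glycolysis was not particular to NK and melanoma cells. Its median was -0.25 in mature migratory DCs, -0.17 in cDC2, -0.09 in mononuclear phagocytes and -0.06 in CD8 T cells. In cDC2 it was 0.0051 when each library was clustered on its own, and in regulatory T cells it was -0.0004. Cycling NK cells were 10.4% and 8.08% after thinning, a ratio of 0.778 (0.436 to 1.38), and 35.1% and 20.9% unthinned. Interferon-gamma response genes had a median of -0.08 (-0.32 to 0.02), with 10 of 13 lower, or -0.20 both as a mean over cells and after thinning. The granzyme Gzmc was 0.423-fold (0.398 to 0.451), with 67.1% of its treated UMIs from 1 cell and log2 ratios between -2.39 and -0.22 over the alternatives. Erh was 0.385-fold (0.243 to 0.592) and the chemotactic receptor Gpr183 0.397-fold (0.248 to 0.616), the latter with a log2 ratio of -0.39 at most 5% mitochondrial UMIs.

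The antibody target was at similar levels in both libraries in regulatory T cells. In treated CD8 T cells it was slightly higher by CPM but not by the thinned share of cells with a UMI, whose ratio was 0.983 (0.855 to 1.13). Tnfrsf4 (ENSMUSG00000029075), on chromosome 4 (156013843 to 156016612, mm10), was at 2124 CPM (2054 to 2197) in control and 2108 (2047 to 2170) in treated regulatory T cells. In CD8 T cells it was at 456 and 492 CPM, 1.08-fold (1.05 to 1.11). After thinning, 84.5% and 81.3% of regulatory T cells had a Tnfrsf4 UMI, against 30.5% and 30.0% of CD8 T cells and 1.30% and 0.177% of melanoma cells, taken as background. Thinning left out 9 and 4 regulatory T cells and 4 and 3 CD8 T cells. Before thinning the median depths were 4770 and 4053 UMIs in regulatory T cells, 12848 and 10184 in CD8 T cells and 76082 and 68035 in melanoma cells. Unthinned, the shares were 97.8% and 96.8% in regulatory T cells. In NK cells Tnfrsf4 rested on 16 and 8 UMIs. Mature migratory DCs held it at 121 CPM in both libraries, mononuclear phagocytes at 20.7 and 15.6 and melanoma cells at 6.06 and 4.02. Of the 7 classes compared, the ligand gene Tnfsf4 was highest in mature migratory DCs, at 28.1 and 28.4 CPM, and in CD8 T cells, at 24.5 and 22.5 CPM, and had 0 UMIs in regulatory T cells of both libraries, which allows up to 2.29 and 1.71 CPM.

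Over all kept cells, which mix composition and level, 3 genes passed the size rule and all were lower. Ccl1 was at 88.4 and 30.5 CPM, 0.345-fold (0.331 to 0.360). Penk, which encodes proenkephalin, was 0.381-fold (0.362 to 0.400), and Iigp1 0.426-fold (0.410 to 0.442).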

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

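With 1 library per group, no library could be left out. No paired analysis was possible because each group holds 1 library. Leaving out melanoma and low-UMI clusters, reclustering mononuclear phagocytes, leaving out their cluster led by T cell genes, summing without melanoma, holding the cluster mix, splitting melanoma cells, Spp1 shares, and thinning or separate clustering for list medians were chosen after seeing the data. The 5 list medians given below were picked after the list medians had been seen. Over the alternatives that gave a value, the share ratio stayed between 0.662 and 0.723 for CD8 T cells, 1.54 and 1.67 for mature migratory DCs and 2.28 and 2.78 for neutrophils. Without doublet removal the ratio was 1.09 for regulatory T cells and 1.08 for plasmacytoid DCs, and cDC2 joined the latter, which shows in their 215 and 273 cells. The ratio for mononuclear phagocytes was 0.951 at most 5% mitochondrial UMIs and 0.976 at Leiden resolution 2.0. For B or plasma cells it was 1.20 at 5% mitochondrial UMIs and 0.282 with separate clustering. Without the 171 genes that differ, the 720 cells of the phagocyte cluster led by Fcrls and Folr2 spread over several clusters, 51.8% of them in 1, so no share ratio is given for them. The ratio of cycling mononuclear phagocytes was 1.10 (0.904 to 1.33) after thinning and 0.868 unthinned. The cause was not tested.

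The interferon-gamma median in mononuclear phagocytes was -0.66 as a mean over cells, -0.65 after thinning, -0.78 with at least 1000 UMIs and -0.67 at 5% mitochondrial UMIs, and -0.38 and -0.52 with the cluster mix of the control and treated library. In melanoma cells it was -1.33 with a pseudocount of 1 CPM, -0.97 after thinning, -1.03 without doublet removal, -0.95 with all members, and -0.81 and -1.27 within clusters 17 and 7 of resolution 2.0. The MHC class I median in mononuclear phagocytes was -0.53 with a pseudocount of 1 CPM, -0.41 both as a mean over cells and after thinning and -0.42 at 5% mitochondrial UMIs, and -0.25 and -0.35 with the cluster mix of the control and treated library. In melanoma cells it was -1.07 with trimmed-mean scaling, -1.06 with a pseudocount of 1 CPM, -1.09 as a mean over cells, -1.11 after thinning, -0.95 both without doublet removal and with all members, and -0.96 and -1.10 within clusters 17 and 7. The G2M median in regulatory T cells was -0.47 as a mean over cells, -0.45 without doublet removal and -0.41 with separate clustering. Of 29 genes named by size, 27 kept their sign throughout. Ccl3 in regulatory T cells was at -0.14 as a mean over cells, -0.20 without doublet removal and -1.94 with separate clustering. Hspa1b in cDC2 was at 0.17 with separate clustering. The cause was not tested. Of all gene log2 ratios over the alternatives, 4907 stayed within their interval, 1128 moved, sign changes of genes not named by size among them, and 4 reversed, which are the Ccl3 and Hspa1b values above. Of other list medians, 1163 stayed within their interval and 314 moved, sign changes among them.

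No value was obtained for cDC2 without doublet removal, for plasmacytoid DCs at resolution 0.5 and with separate clustering, or for gamma-delta T cells at resolution 2.0 and with separate clustering, where the class had no cells in a library. The automatic doublet threshold was not run, as it marked too few barcodes. A minimum of 20 CPM changes no ratio and would add Gzmk and Dynlt1f in NK cells, Gbp2b in mononuclear phagocytes, Mfge8 in mature migratory DCs, Ly75 in cDC2, and Fcrls and Igf1 over all kept cells. Classes of under 100 cells per library are limited by their number of cells.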

Other observations

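Eno1, a glycolytic enzyme, was lower in the treated library in all 7 classes compared. It was 0.706-fold (0.683 to 0.730) in CD8 T cells, 0.772-fold (0.697 to 0.855) in regulatory T cells and 0.559-fold (0.477 to 0.652) in NK cells. In mononuclear phagocytes, mature migratory DCs and cDC2 it was 0.687-fold (0.671 to 0.703), 0.599-fold (0.505 to 0.710) and 0.646-fold (0.582 to 0.716). In cDC2, 11 of 17 type I interferon response genes were higher, with a median of 0.05 that was -0.10 after thinning, while 13 of 14 interferon-gamma response genes were lower. Ifit3 was 1.996-fold (1.50 to 2.67) and Rsad2 1.96-fold (1.49 to 2.60), with 21.3% and 31.2% of their treated UMIs from 1 cell. In cDC1, with 72 control cells, all 15 G2M phase genes were lower in the treated library, with a median of -0.84 (-1.05 to -0.68). Macrophage genes were lower by more in the same cDC1, with 12 of 13 lipid and complement macrophage genes lower and a median of -1.18. The cDC1 medians were -0.37 (-0.58 to -0.24) for interferon-gamma response and -0.24 (-0.30 to -0.205) for MHC class I. In neutrophils, with 53 control cells, 10 of 12 interferon-gamma response genes were lower, with a median of -0.81 (-1.13 to -0.36). Of 16 MHC class I genes 15 were lower in neutrophils, with a median of -0.67 (-0.87 to -0.45). With 53 and 154 neutrophils at median depths of 1712 and 1407 UMIs, a list member at the 10 CPM minimum can rest on very few UMIs. The redraws keep a count of 0 at 0, so these intervals are too narrow. The lists of cDC1 and neutrophils were not run under the alternatives.

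The tests of cluster mix, of Ifng and of unnamed T or NK cells below were chosen after the results they measure had been seen, at least in part, and the 8 tissue-macrophage genes were picked from these libraries. The tests of depth, leukocyte RNA, skin and Foxp3 were fixed before their results were seen. With 1 library per group, a difference between animals, tumours or preparations stays open for every pattern and was not testable.

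The first pattern is the lower interferon-gamma and MHC class I lists in mononuclear phagocytes and melanoma cells. For a difference in depth, every cell was thinned to 1000 UMIs, after which the higher of the 2 interferon-gamma medians was -0.65, in mononuclear phagocytes. Thinning leaves the expected CPM of a cell unchanged and mainly weighs cells alike, and the mean over cells was -0.66 in that class. Classes were still assigned at full depth. The thinned value therefore cannot decide on depth. A changed mix of the 5 phagocyte clusters alone is argued against as the whole cause, as 4 of 5 clusters had an interferon-gamma median below -0.3, with a range of -1.27 to -0.28. The limit of -0.3 was set after the results had been seen. A changed mix of cells within a cluster would also lower these medians and was not tested. With the mix held at that of either library the medians were -0.38 and -0.52 for interferon-gamma, against -0.75, and -0.25 and -0.35 for MHC class I, against -0.50. Genes of these lists were not left out when the clusters were formed. Cxcl9 and Gbp2b are among the top 10 genes of the cluster led by Ccl8 and C1qa. A lower response can thus itself move cells between clusters, so how much the mix carries cannot be told. Leukocyte RNA in melanoma droplets accounted for 5.83% of the difference in the MHC class I total of melanoma cells. A candidate explanation is less interferon-gamma in the tumour, which these libraries do not measure. Ifng over kept cells other than melanoma had a ratio of 0.699 (0.680 to 0.717), but CD8 T cells held 13324 of its 14394 control and 8089 of its 8982 treated UMIs. That ratio thus largely restates the lower CD8 T cell share and is not separate evidence. Within CD8 T cells the Ifng ratio was 0.949, and in NK cells 0.871 (0.731 to 1.04). In regulatory T cells it was 1.65 (1.31 to 2.09) by CPM but 0.818 (0.402 to 1.70) by thinned share of cells with a UMI. Their interferon-gamma list median was 0.10 (-0.06 to 0.19). The RNA was measured and the protein was not, and a share of sorted cells does not give an amount in the tumour.

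The second pattern is the higher level of 8 tissue-macrophage genes in mononuclear phagocytes, namely Apoe, Fcrls, Igf1, Gas6, Cbr2, Folr2, Mrc1 and Stab1. A changed cluster mix may explain part of it and cannot be told apart from a change within cells, as 2 of the 4 other clusters had a median of these genes above 0.3, with a range of -0.05 to 0.74. More skin in the treated sample could also contribute. Keratinocyte and fibroblast markers had a ratio of 1.45 (1.26 to 1.66), mostly from Krt10 and Col1a2 at 2.03 and 1.97 CPM in the treated library. Col1a1 (17 and 29 UMIs), Col3a1 (8 and 24), Pdgfra (4 and 12) and Dcn (5 and 9) were higher too. Dsp (41 and 21 UMIs), Lum (12 and 7) and Krt14 (1 and 0) were lower, and Krt5 and Krt15 had 0 UMIs. The CD45 sort should leave out such cells, but melanoma cells passed it, at 6.41% of control and 8.07% of treated kept cells. The ratio was taken over all kept cells, melanoma cells among them. It therefore does not tell which cells these UMIs came from.

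The third pattern is the lower CD8 T cell and higher regulatory T cell share. Counting every unnamed T or NK cell of the treated library, and none of the control library, as CD8 T left a ratio of 0.843 (0.785 to 0.906), which argues against unnamed clusters as the whole cause. The share of kept cells with a Foxp3 UMI after thinning, which uses no clusters, had a ratio of 1.39 (1.04 to 1.88), from 1.30% and 1.80% of cells. Unthinned it was 4.78% and 5.75%, against 2.08% and 1.42% of melanoma cells, and thinning left out 123 and 114 cells. Of the 76 control and 124 treated cells with a Foxp3 UMI after thinning, 60 and 109 were in the regulatory T class, so largely the same cells were counted. The Foxp3 share was taken after doublet removal and cannot check that step, without which the regulatory T cell ratio was lower. Whether the treatment or the animals set the CD8 T and regulatory T cell shares stays open.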
